A study of Nicotiana tabacum with 4 samples.

How the data were processed

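Small RNA libraries were made from tobacco leaves of the genotypes NC567 and Taiyan8, per the labels' protocols. Seedlings grown in a greenhouse were moved to a growth chamber at 6 °C, 80% humidity and 16 h light with 8 h dark, and the third leaf was taken from 3 plants at 0 h, as control, and after 24 h of cold. About 5 µg of small RNA per group was run on a gel, 18 to 30 nt were cut out, adapters were ligated, and the product was amplified by 15 PCR cycles and sequenced on an Illumina instrument. The labels give 1 library per genotype and time and do not state whether the 3 plants were pooled, so spread between plants cannot be seen. CASAVA 1.4 is named in the submitters' processing notes; the aligner, adapter trimming, counting tool and genome build are not given in the sources used here.

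Each deposited file lists distinct sequences with a whole-number count, a length, the name and resource of the matching RNA, the match type and the number of mismatches, per the file headers. The counts are the authors' raw counts per distinct sequence, and a second column of expression values equals the count in every row. Only annotated sequences are listed, with 15 to 50 nt and at most 2 mismatches to a tobacco miRNA precursor, an Rfam sequence or a sequence of a non-coding RNA collection, so a file's sum is its annotated reads and not the full depth of the library. These sums ran from 2792101 to 4744495 reads over 227410 to 324655 distinct sequences. Reads without molecular identifiers are not independent molecules, so all intervals and limits for a count of 0 (3 reads of the total) cover counting error only.

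Counts of sequences named to 161 tobacco precursors were summed into 53 families by the number in the precursor's name. Sequences that match only the precursor and not its listed mature part stayed in, and made up 36.2 to 40.6% of family reads. They include the most abundant miR6025 sequence, so that family's identity is uncertain, and paralogous precursors of a family share reads. RNA classes were read from the annotation names. No genome of the species was used here, and the gene table of assembly ASM71507v2 holds no miRNA genes, so no coordinates are given.

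Libraries were scaled by TMM factors of the family counts, 0.964 and 0.985 for NC567 and 1.175 and 0.895 for Taiyan8 (0 h and 24 h), on top of the annotated reads per file. Folds between 2 libraries used a prior count of 0.5 and an exact (Clopper-Pearson) 95% interval of the 2 counts, and need 100 reads in 1 of the libraries compared. They have no test. The difference in response is the ratio of 2 such folds, with a normal interval from the 4 counts, since a model with an interaction has no residual degrees of freedom. The shared effect of cold, with genotype as a block, and of genotype, with time as a block, was tested over all 4 libraries by edgeR 4.0.16's quasi-likelihood test (glmQLFit and glmQLFTest, filterByExpr, Benjamini-Hochberg adjusted p under 0.05) in R 4.3.3. That model has 3 coefficients and 1 residual degree of freedom and takes the genotypes' difference in response as error. Its p-values measure the spread between these libraries. DESeq2 1.42.0 and limma 3.58.1 (voom) served as alternatives. Shares, intervals, random lists (10000, matched on expression) and 2-sided permutation tests (100000) were computed in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and statsmodels 0.14.6, and figures were drawn with matplotlib 3.10.9.

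The edgeR fits were tested on simulated data drawn from the real means and depths: for families, 5 of 5 changes of 1.5-fold and 5 of 5 of 2-fold were recovered with 1 false call among 43 unchanged families, and for distinct sequences 9 of 100 of 4-fold and 68 of 100 of 16-fold with 4 false calls among 22466. For the families the prior degrees of freedom were infinite, which makes all families share 1 spread. The simulation gave every feature the fit's common dispersion (0.00867 for families and 0.212 for sequences) and no difference between genotypes. It takes the shared spread as given and so cannot test it or the calls in the real data.

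Before the data were examined, the tests, alternatives, miRNA lists (phase change, leaf development, auxin, copper, nutrient, silencing, defence, cold-reported, other plants, animals) and the naming rule were fixed. The rule names every listed family with at least 100 reads in a library compared, the 10 families with the most reads, and per comparison the 10 largest rises and 10 largest falls with at least 100 reads and an interval that excludes 1; for shared effects, at most 10 per direction past the threshold with the same direction in both pairs, and for distinct sequences at most 3 per direction past it. Listed and abundant families that were not among the 10 largest in a comparison are given there through list medians and counts, not each by name. miR408 for genotype and miR395 and miR397 for cold are named outside this rule, by their lists, and miR1446 for cold, from under 100 reads, because its fold lay above those of named families. Values of single sequences were picked afterwards. Alternatives were other scalings, count minimums of 10 reads or 50 reads in total, no filter, family counts by sequence (reads of 19 to 24 nt beginning with the first 18 nt of a fixed sequence) or by the exact fixed sequences, a prior count of 5, no block, leaving out each library, single sequences as features, and other denominators for shares. Added after seeing the data were sequences with 0 mismatches, mature matches only, reads of 21 and 22 nt, reads of 18 to 30 nt, the similarity without called families, and the snoRNA class. The 2-fold size used to count families is a fixed rule of size, not a test. Counts of snoRNA families were made after the snoRNA share was seen. No unit had to be changed from the one the design assumed.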

Results

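Small RNAs were sequenced from leaves of 2 tobacco (Nicotiana tabacum) genotypes, NC567 and Taiyan8, taken at 0 h, as control, and after 24 h in a growth chamber at 6 °C. Each of the 4 combinations of genotype and time was 1 library, from leaves collected from 3 plants per the labels, so no group had a replicate. The deposited counts listed annotated sequences, and their sums were 2792101 and 4744495 reads for NC567 at 0 h and 24 h, and 3595271 and 4557930 for Taiyan8. Reads named to tobacco miRNA precursors made up 19% and 18.0% of these in NC567 and 23.7% and 19.3% in Taiyan8, and fell into 53 families. Levels are given in RPM over the annotated reads of a library, and scaled RPM also take in its TMM factor. The 10 families with the most reads, miR6025, miR159, miR396, miR6149, miR6145, miR168, miR166, miR6146, miR6161 and miR156, held 90.0% of the family reads, and miR6025 and miR159 alone held 25.3% and 23.4%. Intervals in parentheses are 95% intervals from the counts alone and cover counting error, not variation between plants or libraries.

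The NC567 0 h library stood apart from the other 3 in measures that do not concern gene expression. Reads whose first base was replaced by G had a median share of 0.0440% among abundant miRNA sequences there, against 6.06%, 6.02% and 5.96% in the others. Over abundant sequences of all classes, replacement by T had a median of 0.0742% there, against 16.0%, 14.4% and 15.1%. A second base replaced by C had 1.67% there and 0% in the others. Counts with 0 mismatches or of exact sequences can therefore leave out different reads in that library. The 4 animal miRNAs let-7, miR-21, miR-122 and miR-143 together reached 202 RPM in that library and 10.3, 6.68 and 6.14 in the others. These marks bear on the cold comparison in NC567 and the genotype comparison at 0 h, which use that library. miR444, miR528, miR158 and miR163, miRNAs of other plant groups, had 0 reads in all 4 libraries. This allows up to 1.07 RPM in the shallowest, provided that the resources used for annotation hold these miRNAs. Only annotated sequences were listed, so a miRNA absent from those resources would show 0 at any level.

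**Figure D1:**
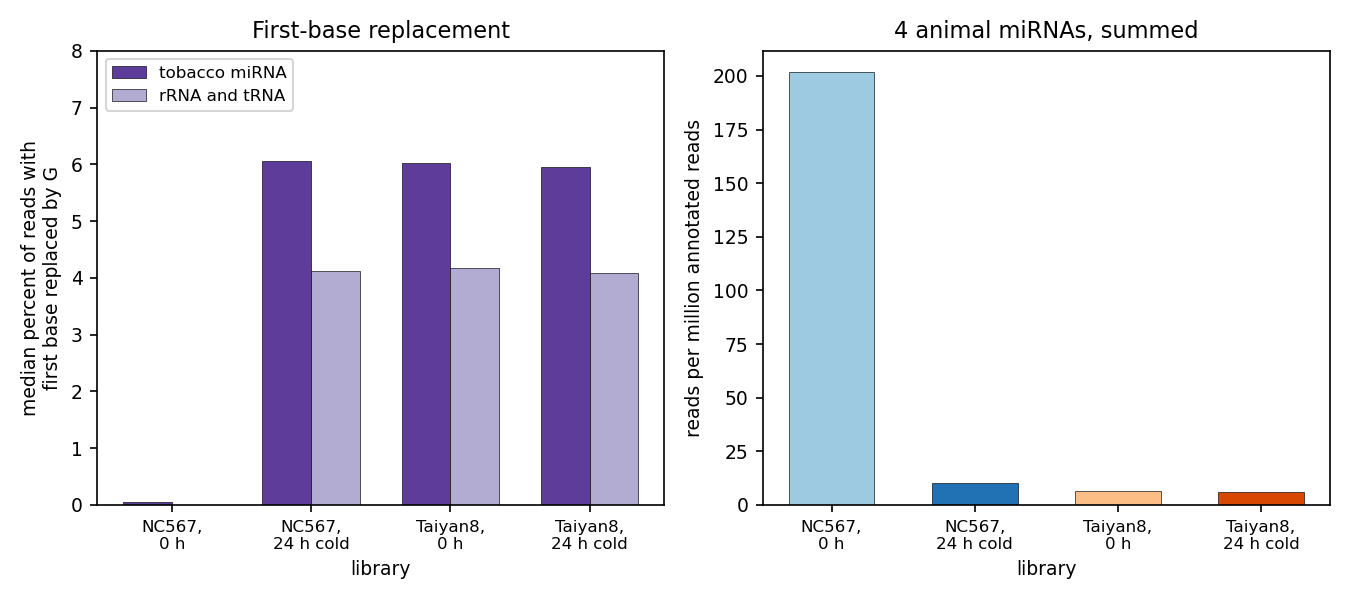
Left, median percent of reads with the first base replaced by G (y axis) over 33 abundant tobacco miRNA sequences (dark) and 58 rRNA and tRNA sequences (light) in each library. Right, RPM over annotated reads of 4 animal miRNAs summed, which reached 202 in the NC567 0 h library and at most 10.3 in the others.

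In NC567, the first comparison asked how 24 h of cold changed the miRNA profile. miR408, miR399 and miR398 stood highest after cold: miR408, a copper-responsive family that targets plantacyanin and laccase mRNAs, was 3.60-fold (2.78 to 4.78) its 0 h level, miR399, which targets the phosphate regulator PHO2, 2.80-fold (2.19 to 3.67), and miR398, a copper-responsive family that targets copper superoxide dismutase mRNAs, 2.73-fold (2.34 to 3.20). On the other side, miR477 stood at 0.398-fold (0.326 to 0.485) and miR169, which targets mRNAs of NF-YA transcription factors, at 0.432-fold (0.401 to 0.464) of the 0 h level. miR156, which targets SPL mRNAs and is the main miRNA of the juvenile phase, went from 6008 to 3919 scaled RPM, 0.652-fold (0.639 to 0.666).

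Apart from miR156, these were the 5 families at least 2-fold apart among 51 with 100 or more reads in a library. Smaller values above 1 were those of miR479, 1.34-fold (1.27 to 1.42), miR482, which targets mRNAs of NBS-LRR resistance genes, 1.28-fold (1.24 to 1.31), miR6158, 1.18-fold (1.01 to 1.38), miR6150, 1.17-fold (1.06 to 1.29), miR162, 1.09-fold (1.02 to 1.17), miR6153, 1.08-fold (1.03 to 1.13), and miR396, 1.08-fold (1.06 to 1.09). Below 1 were miR827, 0.682-fold (0.577 to 0.808), miR6154, 0.719-fold (0.575 to 0.901), miR6148, 0.728-fold (0.620 to 0.855), miR6019, 0.779-fold (0.675 to 0.901), miR6157, 0.805-fold (0.675 to 0.963), miR168, which targets AGO1, 0.822-fold (0.812 to 0.833), and miR166, which targets HD-ZIP III mRNAs, 0.846-fold (0.832 to 0.860). The 2 measured copper families had a median log2 fold of 1.65, at percentile 100 of 10000 random lists matched on expression, and the 6 leaf development families (miR159, miR166, miR171, miR319, miR394, miR396) a median of -0.23, at percentile 2.87. The miR166 value covers only reads named to tobacco precursors, which had 24094 and 35370 reads in NC567 at 0 h and 24 h. Outside those names, the most abundant sequence with the miR166 prefix had 32489 and 72418. Its fold in RPM was 1.31 in NC567 and 0.815 in Taiyan8. The lower miR166 value in NC567, and its part in the leaf development median, thus hold for the named reads only. The comparison has no replicate check and 1 library on each side. With mature matches only, the log2 fold of miR399 in NC567 was -0.18 in place of 1.49, and by sequence it was 0.37. Its reads after cold were 63 mature and 299 from the rest of the precursor. The log2 fold of miR408 was 0.18 in the shorter exact sequence fixed in advance, in place of 1.85. It was 1.89 by sequence, 2.30 in mature matches only and 2.29 in reads of 21 and 22 nt.

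In Taiyan8 the same families led the cold comparison among those with 100 or more reads in a library. miR399 was 2.91-fold (2.38 to 3.59) its 0 h level, miR398 1.72-fold (1.56 to 1.91) and miR408 1.57-fold (1.32 to 1.86), while miR477 stood at 0.328-fold (0.255 to 0.416), miR169 at 0.381-fold (0.345 to 0.419) and miR156 at 0.723-fold (0.705 to 0.741). miR399, miR477 and miR169 were the 3 families at least 2-fold apart among 48. Below that minimum in both libraries, miR397, a copper-responsive family that targets laccase mRNAs, was 2.52-fold (1.20 to 6.04) its 0 h level, miR1446 2.35-fold (1.38 to 4.25) and miR395, which targets ATP sulfurylase mRNAs, 1.62-fold (1.15 to 2.34). By sequence, the log2 fold of miR399 was 0.66 in place of 1.54.

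Other values above 1 in Taiyan8 were those of miR6024, 1.32-fold (1.17 to 1.5), miR390, which starts the trans-acting siRNAs that target auxin response factors, 1.31-fold (1.19 to 1.45), miR6158, 1.28-fold (1.11 to 1.48), and miR162, which targets DCL1, 1.22-fold (1.15 to 1.29). miR167, which targets auxin response factor mRNAs, 1.26-fold (1.23 to 1.28), miR482, 1.24-fold (1.21 to 1.27), miR6159, 1.22-fold (1.17 to 1.29), miR6150, 1.22-fold (1.13 to 1.31), miR827, 1.21-fold (1.08 to 1.34), and miR479, 1.13-fold (1.08 to 1.19), also lay above 1, and of these values those of miR162, miR167, miR482, miR479, miR827, miR6150, miR6158 and miR6159 changed sign without the TMM factor. Below 1 were miR6157, 0.827-fold (0.699 to 0.977), miR6162, 0.832-fold (0.742 to 0.931), miR160, 0.889-fold (0.804 to 0.983), miR6020, 0.900-fold (0.840 to 0.964), miR171, 0.931-fold (0.879 to 0.986), miR6151, 0.921-fold (0.852 to 0.997), and miR6146, 0.928-fold (0.914 to 0.943). The median log2 fold of the 4 nutrient families (miR169, miR395, miR399, miR827) was 0.49, at percentile 98.2, over members that went both ways. Leaving out the TMM factor moved the median of all families by -0.39 log2 in Taiyan8 and DESeq2's size factors moved it by -0.11, and 24 of the 48 folds changed sign without the factor.

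Over both genotypes, 8 of the 53 families changed with cold, 5 rising and 3 falling, by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. The families that rose were miR399 (log2 fold 1.52 ± 0.18, adjusted p = 1.1e-09), miR408 (log2 fold 1.16 ± 0.18, adjusted p = 2.2e-07), miR398 (log2 fold 1.09 ± 0.13, adjusted p = 1.1e-09), miR482 (log2 fold 0.33 ± 0.11, adjusted p = 0.030) and miR479 (log2 fold 0.30 ± 0.10, adjusted p = 0.030), and each was higher in 2 of 2 genotypes. Those that fell were miR477 (log2 fold -1.46 ± 0.18, adjusted p = 1.9e-09), miR169 (log2 fold -1.30 ± 0.11, adjusted p = 2.3e-14) and miR156 (log2 fold -0.54 ± 0.12, adjusted p = 0.00038), lower in 2 of 2 genotypes. The ± values, here and for genotype, are approximate standard errors, the size of the fitted log2 fold over the square root of the test's F statistic. They rest on a spread taken as common to all families and not on how far a family's own folds lie apart. In NC567 and Taiyan8 the log2 folds were 1.85 and 0.65 for miR408 and 1.45 and 0.79 for miR398. Without the TMM factor, the folds of miR482 and miR479 in Taiyan8 changed sign. Their calls passed in 4 and 3 of 10 other settings with the block (adjusted p 0.030 to 0.82 and 0.018 to 0.82). With sequences of 0 mismatches only, miR398 had a shared log2 fold of 0.35 and did not pass (adjusted p = 0.27, 1.1e-09 to 0.27 over 10 settings with the block). With mature matches only, miR399 had 0.60 and did not pass (adjusted p = 0.62, 1.1e-09 to 0.62 over those settings). Without the NC567 cold library and the block, miR169 had a log2 fold of -1.95, and without the Taiyan8 0 h library and the block, miR408 had 1.80. Other such fits gave smaller folds. Without NC567 0 h, miR169 had -0.80, miR398 0.66 and miR408 0.66, and without NC567 cold miR479 had 0.06. The fold of miR156 ran from -0.16 without NC567 0 h to -0.95 without NC567 cold. With a library left out and no block, a cold fold also takes in part of the genotype difference.

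By the lists of miRNAs fixed in advance, 2 of the 3 copper families rose (miR398, miR408) and miR397, with under 100 reads in every library, had a fitted log2 fold of 1.27 ± 0.53 that did not pass (adjusted p = 0.11 by edgeR's quasi-likelihood test); adjusted over the list alone, 3 of 3 passed. Of the 4 nutrient families, miR399 rose, miR169 fell, and miR395 (0.46 ± 0.21) and miR827, which targets SPX-domain protein mRNAs (-0.10 ± 0.14), did not pass; adjusted over the list alone, 3 passed. In the phase change list miR156 fell, and miR172, which targets AP2-like mRNAs, had a log2 fold of 0.04 ± 0.15; 1 of 2 passed adjusted over the list alone. Of 4 defence families with reads, miR482 rose and miR6019, miR6020 and miR6025 had log2 folds of -0.13 ± 0.15, -0.07 ± 0.11 and 0.02 ± 0.32, with 1 past the threshold adjusted over the list alone. None of 6 leaf development, 4 auxin (miR160, miR164, miR167, miR390) and 2 silencing families (miR162, miR168) passed this test, either over all families or adjusted over the list alone, and 12 of 53 families had an unadjusted p under 0.05. Of the 9 families listed in advance as reported for cold in Arabidopsis, 7 had a tobacco precursor name. Among these 7, miR408 rose and miR169 fell, and miR166, miR172, miR319, miR396 and miR397 did not pass. Adjusted over the list alone, 3 passed. Members of the other lists without a tobacco precursor name are not counted either. The shared median log2 fold of the copper list lay at percentile 99.7 of random lists, that of the nutrient list at 87.0, silencing at 68.2, auxin at 73.6, cold-reported at 41.0, defence at 34, phase change at 9.21 and leaf development at 8.56.

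The p-values rest on 1 residual degree of freedom and a spread that edgeR took as common to all families (biological coefficient of variation 9.31%), and the counts of calls changed with it. DESeq2's Wald test gave 3 higher and 3 lower and limma-voom 4 and 3, whereas edgeR called 0 families without the genotype as a block (6 at unadjusted p under 0.05), 0 with miRNA reads as the library size (10), and 0 in the families' mature matches alone (9). Leaving out each library in turn, also without the block, gave 0 higher and 0 to 2 lower.

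**Figure D2:**
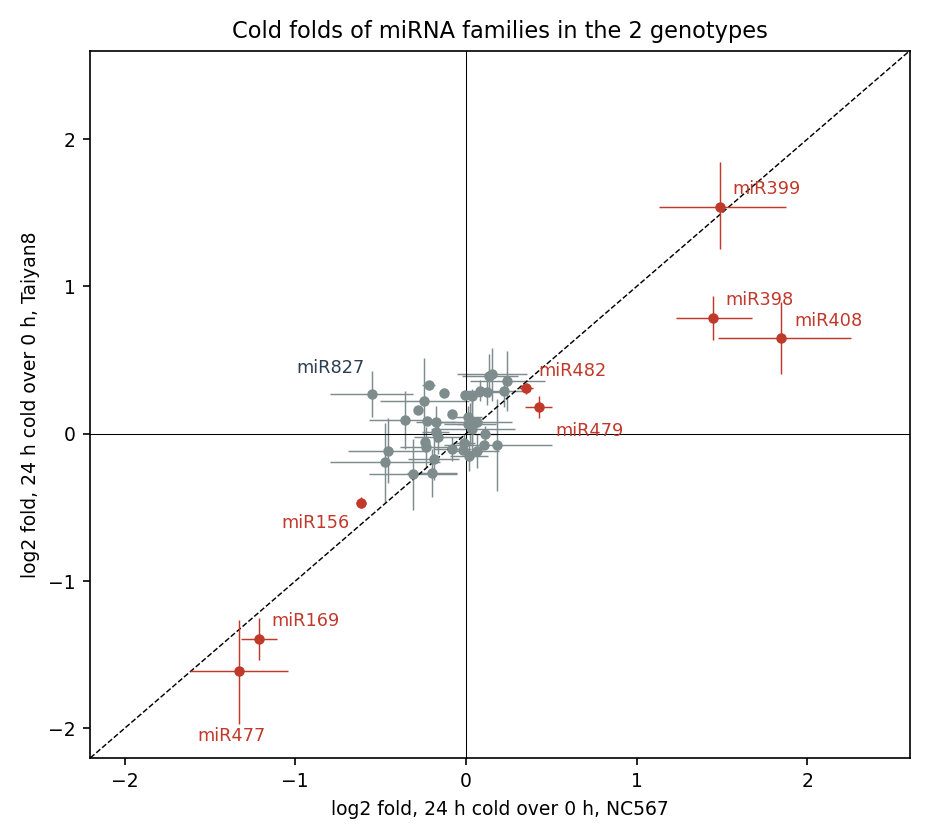
Log2 fold of 24 h cold over 0 h in NC567 (x axis) and Taiyan8 (y axis) for 48 miRNA families with at least 100 reads in each pair, bars showing 95% counting intervals. Red points passed edgeR's shared test (adjusted p under 0.05), grey points did not, and the dashed line marks equal folds; miR408 lies at 1.85 and 0.65 and miR477 at -1.33 and -1.61.

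**Figure D3:**
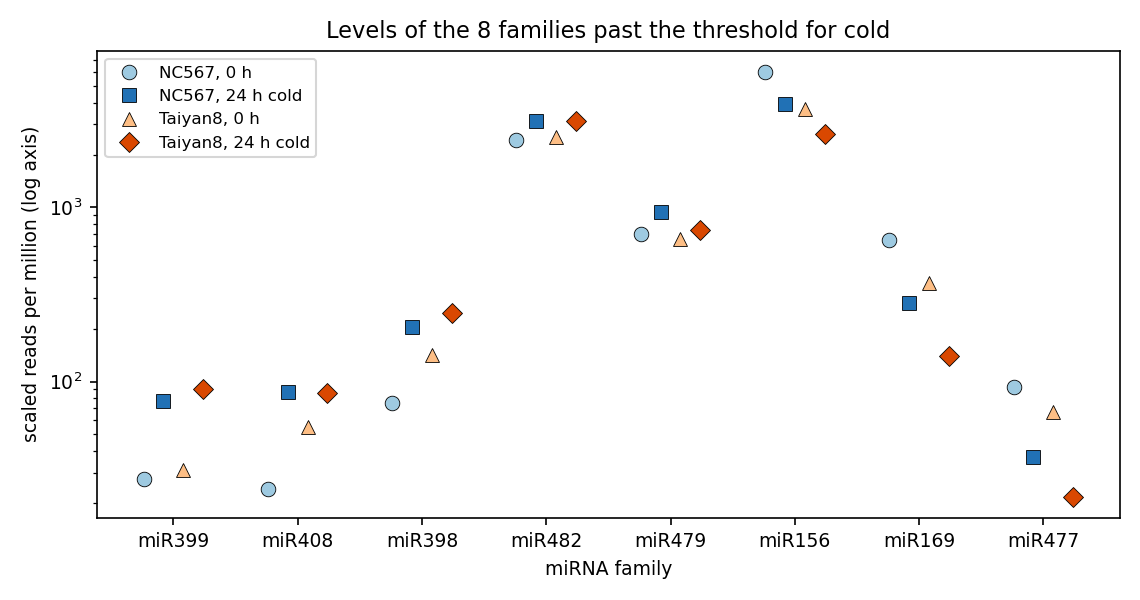
Scaled RPM (log axis) of the 8 families past the threshold for cold in each of the 4 libraries, 1 point per library. miR399 goes from 27.5 to 77.4 in NC567 and from 31 to 90.4 in Taiyan8.

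The most abundant sequence held 66.4% of the family's reads for miR398, 32.5% for miR408, 57.9% for miR169, 67.7% for miR156, 37.2% for miR477 and 40.5% for miR399. That of miR398, TATGTTCTCAGGTCGCCCCTG, matched with 1 mismatch and had 149 and 704 reads in NC567 and 312 and 674 in Taiyan8 (0 h and 24 h in each), and that of miR408, TGCACTGCCTCTTCCCTGGCT, 18 and 140 reads in NC567 and 80 and 105 in Taiyan8. The most abundant miR169 sequence, TAGCCAAGGATGACTTGCCT, had 927 and 724 reads in NC567 and 1011 and 350 in Taiyan8, that of miR156, TTGACAGAAGATAGAGAGCAC, 11182 and 12203 reads in NC567 and 10537 and 7216 in Taiyan8, and that of miR477, CCTCTCCCTCAAGGGCTTCTC, 80 and 70 reads in NC567 and 113 and 32 in Taiyan8. For miR399 the most abundant sequence was GGGCTACTCTCTATTGGCATG, listed under the precursors but not as their mature miRNA, with 17 and 158 reads in NC567 and 44 and 160 in Taiyan8, while the listed mature sequence CGCCAAAGGAGAGCTGCCCTG had 41 and 60 reads in NC567 and 24 and 63 in Taiyan8.

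Cold folds of the genotypes resembled each other across families. Over 48 families Pearson's r was 0.81 and Spearman's rho 0.59 (permutation p = 1e-05, the smallest that 100000 permutations give, and 6e-05; 1.5e-05 and 9e-05 after Benjamini-Hochberg adjustment over 6 relations). This is a correlation across families, which are not independent replicates, and 32 of the 48 had folds of the same sign. Without miR408 and miR399, the families farthest from the NC567 median, r was 0.79 (permutation p = 1e-05), and without the 8 called families it was 0.32 (permutation p = 0.043).

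How far the genotypes differed in their response was read from the ratio of the Taiyan8 fold to the NC567 fold, with no test. miR408 had the only ratio of at least 2-fold, a log2 ratio of -1.20 (-1.65 to -0.76), and started lower in NC567: 24.1 to 87.5 scaled RPM there against 54.9 to 86.0 in Taiyan8. miR398 had a log2 ratio of -0.66 (-0.92 to -0.40) with levels of 75.0 to 205 and 143 to 247. The highest ratio was that of miR827, 0.82 (0.54 to 1.11), followed by miR167, 0.55 (0.50 to 0.60), miR319, 0.47 (0.08 to 0.85), miR6019, 0.45 (0.17 to 0.73), miR168, 0.44 (0.41 to 0.47), and miR6145, 0.41 (0.39 to 0.44). The last of these, with miR159, 0.31 (0.30 to 0.33), miR6149, 0.27 (0.24 to 0.29), miR6148, 0.34 (0.03 to 0.66), and miR390, 0.26 (0.04 to 0.47), changed sign without the TMM factor, which moved the median log2 ratio of all families by -0.42. Lower ratios were those of miR479, -0.25 (-0.35 to -0.14), miR6151, -0.19 (-0.35 to -0.02), miR396, -0.18 (-0.21 to -0.16), miR169, -0.18 (-0.35 to -0.01), miR6020, -0.17 (-0.31 to -0.02), miR6153, -0.11 (-0.20 to -0.03), and miR6146, -0.09 (-0.13 to -0.06). miR399 and miR477 had ratios whose intervals included 0, 0.05 (-0.41 to 0.51) and -0.28 (-0.72 to 0.16), that of miR399 changing sign under each of the 3 other scalings. The miR408 ratio had the opposite sign, 0.36, in the shorter exact sequence fixed in advance, and was -1.81 in mature matches only. Every ratio named here uses the NC567 0 h library.

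Before cold, the largest differences between genotypes were in miR395 and miR408. miR395 in Taiyan8 stood at 0.291-fold (0.206 to 0.402) of its NC567 level (12.8 against 44.2 scaled RPM), and miR408 was 2.26-fold (1.72 to 3.04) its NC567 level in Taiyan8. miR398, 1.90-fold (1.62 to 2.25), miR6163, 1.62-fold (1.39 to 1.89), miR827, 1.56-fold (1.35 to 1.81), miR6150, 1.49-fold (1.35 to 1.65), miR171, which targets mRNAs of GRAS transcription factors, 1.48-fold (1.38 to 1.59), miR172, 1.44-fold (1.23 to 1.70), and miR6144, 1.22-fold (1.11 to 1.34), were also higher in Taiyan8. Lower there were miR169, 0.561-fold (0.524 to 0.601), miR319, which targets TCP mRNAs, 0.575-fold (0.468 to 0.705), miR156, 0.609-fold (0.596 to 0.623), miR6162, 0.690-fold (0.619 to 0.770), miR168, 0.706-fold (0.696 to 0.716), miR477, 0.722-fold (0.606 to 0.859), miR6019, 0.818-fold (0.708 to 0.947), and miR6148, 0.830-fold (0.708 to 0.975). Among abundant families, miR159, which targets GAMYB mRNAs, was 1.29-fold (1.28 to 1.30), miR166 1.20-fold (1.18 to 1.22) and miR6161 0.859-fold (0.841 to 0.878), and miR6148 and miR6161 changed sign without the TMM factor, which shifted the median of all families by 0.29 log2. Of 49 families, 2 were at least 2-fold apart. The comparison has 1 library on each side and includes the NC567 0 h library.

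After 24 h of cold, miR827 was 2.76-fold (2.41 to 3.16) its NC567 level in Taiyan8, and miR395 and miR169 stood at 0.383-fold (0.295 to 0.490) and 0.495-fold (0.448 to 0.547). These were the 3 of 51 families at least 2-fold apart. Higher in Taiyan8 were also miR6163, 1.67-fold (1.47 to 1.89), miR159, 1.60-fold (1.59 to 1.61), miR6150, 1.56-fold (1.45 to 1.68), miR171, 1.46-fold (1.37 to 1.55), miR172, 1.43-fold (1.25 to 1.64), miR167, 1.41-fold (1.38 to 1.44), miR166, 1.36-fold (1.34 to 1.38), miR6154, 1.36-fold (1.11 to 1.67), and miR6144, 1.35-fold (1.24 to 1.46). Lower were miR164, which targets NAC mRNAs, 0.537-fold (0.381 to 0.741), miR6156, 0.586-fold (0.413 to 0.817), miR477, 0.594-fold (0.454 to 0.770), miR6162, 0.659-fold (0.592 to 0.732), miR156, 0.675-fold (0.659 to 0.691), miR6147, 0.754-fold (0.615 to 0.920), miR479, 0.793-fold (0.757 to 0.831), and miR319, 0.794-fold (0.661 to 0.95). miR408, 2.26-fold at 0 h, stood at 0.983-fold (0.850 to 1.14) with the TMM factor. Dividing by miRNA reads moved the median of all families by -0.24 log2 and leaving out the TMM factor by -0.14, and this changed the sign of none of the families named for this time.

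Across both times, 17 of the 53 families differed between genotypes by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 9 higher and 8 lower in Taiyan8. Highest was miR827 (log2 fold 1.06 ± 0.14, adjusted p = 3.3e-08), followed by miR6163 (log2 fold 0.72 ± 0.14, adjusted p = 5.1e-05), miR6150 (log2 fold 0.61 ± 0.12, adjusted p = 2.5e-05), miR398 (log2 fold 0.56 ± 0.13, adjusted p = 0.00055), miR171 (log2 fold 0.55 ± 0.11, adjusted p = 2.5e-05) and miR172 (log2 fold 0.52 ± 0.15, adjusted p = 0.0052). miR6144 and miR1919 were higher by log2 folds of 0.36 ± 0.12 and 0.32 ± 0.10. miR408 passed (log2 fold 0.45 ± 0.17, adjusted p = 0.041) although it was higher in Taiyan8 at 1 of 2 times. It also passed in 2 of 10 other settings with the block (adjusted p 0.041 to 0.68). Lowest was miR395 (log2 fold -1.56 ± 0.22, adjusted p = 3.4e-08), then miR169 (log2 fold -0.92 ± 0.11, adjusted p = 2.6e-09), miR6156 (-0.84 ± 0.25), miR164 (-0.76 ± 0.25), miR156 (log2 fold -0.64 ± 0.12, adjusted p = 2.5e-05), miR477 (-0.59 ± 0.18), miR6162 (-0.57 ± 0.13) and miR319 (-0.56 ± 0.17). Apart from miR408, each had the same direction at 2 of 2 times. With sequences of 0 mismatches only, the log2 fold of miR398 was 1.38.

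By list, of 3 copper families miR398 was higher in Taiyan8 and miR408 passed with the limits given above (2 passed adjusted over the list alone). Of the 4 nutrient families miR827 was higher and miR395 and miR169 lower (3 adjusted over the list alone). In the phase change list miR172 was higher and miR156 lower, 2 of 2 adjusted over the list alone. Of 6 leaf development families miR171 was higher and miR319 lower (2 adjusted over the list alone), and of 4 auxin families miR164 was lower (1). Of the 7 cold-reported families with a tobacco precursor name, miR172 was higher, miR169 and miR319 were lower, and miR408 passed with the same limits (5). None of 4 defence and 2 silencing families passed this test, adjusted over all families or over the list alone. Shared medians lay at percentile 95.0 for the copper list, 87.8 for leaf development, 82.3 for cold-reported, 46.7 for phase change, 46.0 for defence, 35.9 for silencing, 29.7 for auxin and 9.06 for nutrient families. edgeR's calls, 9 higher and 8 lower, became 2 and 2 without the TMM factor, 0 and 2 with miRNA reads as the library size, and 0 and 0 without time as a block (14 families at unadjusted p under 0.05) or with any library left out (3 to 7), while DESeq2's Wald test gave 8 and 5 and limma-voom 8 and 8. Without the NC567 0 h library and the block, the log2 folds of miR398, miR408 and miR477 turned sign, to -0.074, -0.31 and 0.27, and that of miR169 was -0.16. Without Taiyan8 cold those of miR408 and miR477 turned, to -0.039 and 0.057. Without Taiyan8 0 h those of miR169 and miR477 were -1.84 and -1.65. Without NC567 cold those of miR398 and miR408 were 1.31 and 1.48.

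A further 5 regulatory small RNAs outside the tobacco precursor names were followed by their sequence. miR403, which targets AGO2, was among the abundant ones, at 5240 scaled RPM in NC567 at 0 h, and after cold was 1.10-fold (1.08 to 1.12) in NC567 and 1.10-fold (1.08 to 1.12) in Taiyan8. miR393, which targets auxin receptor mRNAs, was 1.06-fold (0.970 to 1.15) and 1.23-fold (1.13 to 1.34). miR165 was 1.28-fold (0.992 to 1.68) and 0.987-fold (0.801 to 1.22), and the trans-acting siRNA that targets auxin response factors 1.31-fold (1.01 to 1.71) and 1.03-fold (0.840 to 1.26). Without the TMM factor these Taiyan8 folds for cold lie lower by the shift given above, which takes miR403, miR393 and this siRNA below 1. miR828 had 0 reads in all 4 libraries, which would also be seen if the annotation resources lacked it.

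Every distinct sequence past the count filter was also tested. Of 22666 sequences, edgeR's quasi-likelihood test called 0 for cold and 0 for genotype at an adjusted p under 0.05, with 2062 and 1889 at an unadjusted p under 0.05. DESeq2's Wald test called 1 higher and 0 lower for cold and 3 and 2 for genotype, and limma-voom 128 higher and 192 lower for cold and 5 and 9 for genotype. At an unadjusted p under 0.05 for cold by edgeR's test, 21 sequences of 15 to 18 nt were higher and 479 lower of 3124 tested. Of 1864 sequences of 35 to 50 nt, 744 were higher and 10 lower. At 21 nt only 11 were higher and 41 lower of 2220 tested. In simulated counts that gave all sequences 1 common spread, 9 of 100 changes of 4-fold and 68 of 100 of 16-fold were recovered. The cold calls rose to 2219 higher and 1098 lower without the Taiyan8 0 h library, a fit in which the NC567 0 h library alone stood for 0 h, and to 230 and 133 without the NC567 0 h library; for genotype they rose to 1280 and 666 without the NC567 cold library.

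The size and class of the reads differed after cold in both genotypes, with more long reads and fewer very short ones. tRNA reads went from 36.4% to 48.9% of annotated reads in NC567 and from 42.5% to 50.9% in Taiyan8. Reads of 31 to 34 nt, the length of tRNA fragments cut near the anticodon, went from 24.4% to 36.4% and from 31.7% to 39.8%, while those of 15 to 18 nt went from 19.4% to 6.54% and from 13.0% to 6.19%. Reads of 35 to 50 nt went from 3.93% to 10.8% and from 3.71% to 7.13%, and at this length the share of tRNA was 2.81-fold and 1.93-fold and that of rRNA 2.57-fold and 1.88-fold its 0 h value. rRNA reads went from 33.1% to 24.0% in NC567 and from 22.7% to 21.3% in Taiyan8, and tobacco miRNA reads from 19% to 18.0% and from 23.7% to 19.3%. Among reads of 18 to 30 nt, 2 of these differences turned: rRNA in Taiyan8 was higher after cold by 4.74 percentage points and tobacco miRNA in NC567 by 3.89. Over distinct sequences rRNA in Taiyan8 was higher by 4.38. The 95% Clopper-Pearson interval of each share reaches at most 0.0565 percentage points above it.

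The tRNA fragment of 31 to 34 nt with the most reads, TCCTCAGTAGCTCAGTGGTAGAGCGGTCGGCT, went from 47480 to 218095 reads in NC567 (2.70-fold in RPM) and from 196120 to 339489 in Taiyan8 (1.37-fold). The rRNA sequence of at most 18 nt with the most reads, CCGGTCGTCTCGTCCCT, went from 143543 to 51518 (0.211-fold in RPM) and from 123237 to 27711 (0.177-fold). Both were chosen after their values were seen. At 21 nt the share went from 17.2% to 16.2% and from 21.1% to 17.6%, and at 24 nt from 3.30% to 3.05% and from 2.81% to 2.74%. These differences at 21 and 24 nt changed sign in both genotypes without rRNA, tRNA, snRNA and snoRNA reads, and in NC567 also over distinct sequences. Among reads of 18 to 30 nt they changed sign in NC567, and at 24 nt in Taiyan8. With 2 libraries against 2, no permutation test of these shares can give a p below 0.333 when 2-sided. The files list reads of 15 to 50 nt although the labels state that 18 to 30 nt were cut from the gel, and among reads of 18 to 30 nt alone tRNA differed by 0.726 and 0.454 percentage points.

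**Figure D4:**
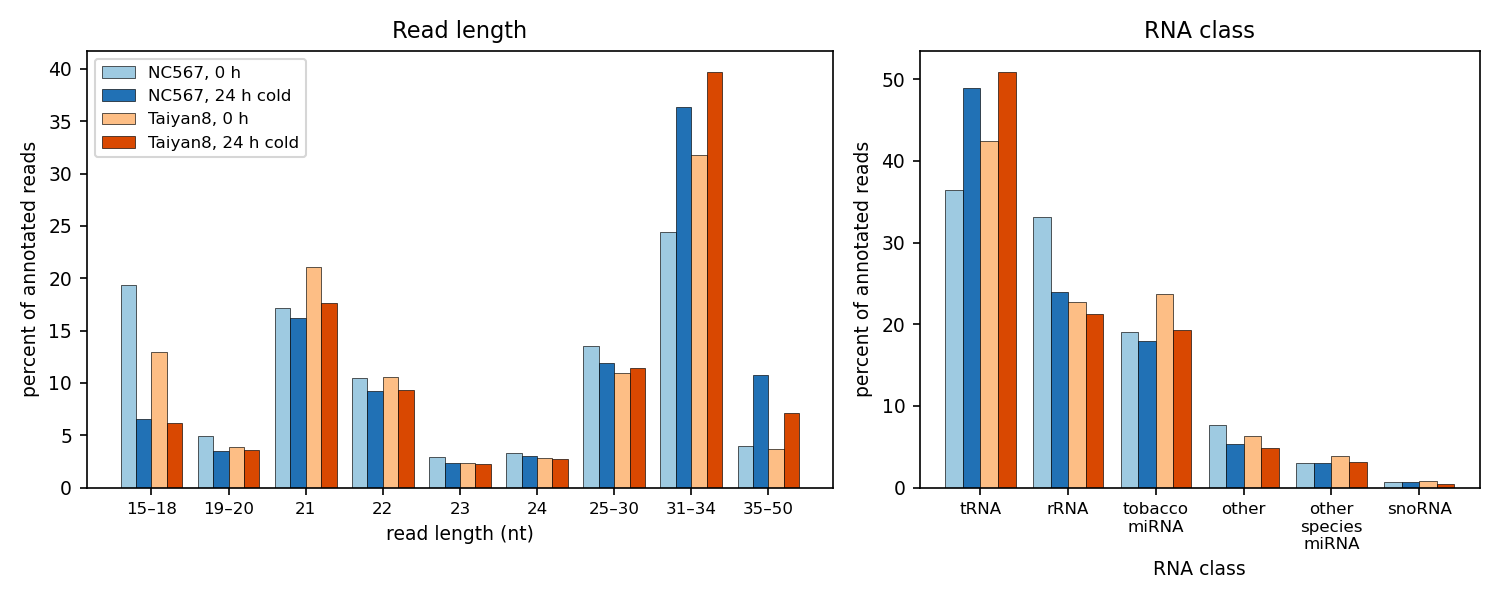
Percent of annotated reads (y axis) by read length in nt (left) and by RNA class (right) in the 4 libraries, 1 bar per library. Bars for 31 to 34 nt stand at 24.4% and 31.7% at 0 h and 36.4% and 39.8% after cold in NC567 and Taiyan8.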

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

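The test on animal miRNAs and the counts of snoRNA families were chosen after the results were seen. Fragments of small nucleolar RNAs (snoRNAs), which guide the modification of rRNA, took 0.788% of Taiyan8 reads at 0 h and 0.420% after cold, against 0.651% and 0.690% in NC567. The shares of reads moved in opposite directions, but those of distinct sequences were lower in both, differing by -0.0246 percentage points in NC567 and -0.533 in Taiyan8. The log2 ratio of the read folds was -0.99, and this difference between genotypes was not tested. Of 34 snoRNA families with at least 400 reads in total, 32 were lower after cold in Taiyan8 (median log2 fold -0.84, with no TMM factor) and 13 in NC567 (median 0.16). snoZ266 went from 732 to 305 RPM in Taiyan8 and from 655 to 728 in NC567, and SNORD96 from 425 to 219 and from 318 to 366. snoU13 and snoR118 were the 2 families higher after cold in Taiyan8, and SNORA51 was among those lower in both genotypes (-1.85 in Taiyan8 and -1.49 in NC567).

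Cold folds of 7 miRNA families had opposite signs in the genotypes, with counting intervals excluding 1 in both and no test of the difference. On the log2 scale in NC567 and Taiyan8 they were miR827 (-0.55 and 0.27, difference 0.82), miR167 (-0.22 and 0.33, difference 0.55), miR168 (-0.28 and 0.16, difference 0.44), miR6145 (-0.13 and 0.28, difference 0.41), miR159 (-0.23 and 0.08, difference 0.31), miR6025 (-0.08 and 0.13, difference 0.22) and miR396 (0.11 and -0.08, difference -0.18). miR396 kept opposite signs under 3 of 3 other scalings, miR827, miR167, miR168 and miR6145 under 2, miR6025 under 1 and miR159 under 0. Its opposite signs came from the sum of 2 kinds of reads, neither of which moved clearly in opposite directions (here miR396). Mature miR396 reads were 1.20-fold (1.18 to 1.21) in NC567 and 0.995-fold (0.983 to 1.01) in Taiyan8. The other miR396 precursor reads were lower in both, at 0.634-fold and 0.704-fold. The difference was largest for miR827, whose levels were 96.5 to 65.9 scaled RPM in NC567 and 151 to 182 in Taiyan8.

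Reads of animal miRNAs appeared in the NC567 0 h library above the limit of a count of 0: miR-143 had 461 reads, let-7 77 and miR-21 25, and miR-122 had 0. In the other 3 libraries the 4 markers summed to 49, 24 and 28 reads, and 3 of them were at least 5 times any other library's level in NC567 0 h. Whether RNA or reads from an animal sample reached that library cannot be told: outside these 4 only 4 animal miRNA families had 10 or more exact reads in total, of which 1 stood at least 5 times above every other library there, and 0 in any other library. A separate sequencing or library batch is a candidate explanation for its standing apart: the median share of reads with a first-base G in rRNA and tRNA sequences was 0% there and 4.09% in the lowest other library. The labels give no batch, both explanations can hold together, and a biological explanation was not tested.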

How the results depend on the processing

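Tests with 0 mismatches, mature matches, 21 and 22 nt or 18 to 30 nt, the similarity without called families, and the snoRNA class, were chosen after the data were seen. Directions of the shared folds, each fitted over all 4 libraries, held more firmly than calls. Within 1 genotype some cold folds of called families did turn. They were those of miR479 and miR482 in Taiyan8 without TMM, and that of miR399 in NC567 in mature matches only. For the 25 calls of named families in the shared tests, no alternative with all 4 libraries reversed a direction; adjusted p stayed under 0.05 in 155 pairs of family and setting, was above it in 212, and the sign reversed in 5, all with 1 library left out. Those 5 are log2 folds for genotype: miR398 (-0.074), miR408 (-0.31) and miR477 (0.27) without NC567 0 h, and miR408 (-0.039) and miR477 (0.057) without Taiyan8 cold; at the other end these reached 1.31 and 1.48 for miR398 and miR408 without NC567 cold and -1.65 for miR477 without Taiyan8 0 h. miR169 kept its sign, at -0.16 without NC567 0 h and -1.84 without Taiyan8 0 h. These fits have no block, so the genotype left with 1 library is read at 1 time only. The genotype fold then takes in part of the family's cold fold, and these moves cannot tell the 2 apart. Counts of shared family calls for cold, 5 higher and 3 lower, became 3 higher and 4 lower without TMM, 3 higher and 3 lower with DESeq2's Wald test, 0 higher and 0 lower with no replicate block, 0 higher and 0 lower with miRNA reads as library size, 0 higher and 0 lower over single sequences, 0 higher and 0 lower in mature matches and 1 higher and 0 lower at 21 and 22 nt. Those for genotype, 9 and 8, became 2 higher and 2 lower, 8 higher and 5 lower, 0 higher and 0 lower, 0 higher and 2 lower, 0 higher and 0 lower, 0 higher and 1 lower and 4 higher and 4 lower in the same order. For cold, where edgeR called 0 with no block, miRNA reads, single sequences and mature matches, 6, 10, 39 and 9 families or sequences had an unadjusted p under 0.05. For genotype the same settings had 14, 18, 72 and 15, where miRNA reads gave 2 lower calls and mature matches 1. Without each library in turn and with no block, cold gave 0 to 0 higher and 0 to 2 lower and genotype 0 to 0 and 0 to 0; the lone library of an arm is then assumed to vary like the others. For distinct sequences, where edgeR called 0, DESeq2 gave 1 higher and 0 lower for cold and 3 higher and 2 lower for genotype, limma-voom 128 higher and 192 lower and 5 higher and 9 lower, and no count filter 960 higher and 577 lower and 494 higher and 525 lower. Leaving out single libraries gave 0 to 2219 higher and 0 to 1098 lower for cold and 0 to 1280 and 0 to 666 for genotype. DESeq2 set the adjusted p of 19335 sequences for cold and 11865 for genotype to NA.

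Families at least 2-fold apart were 5 for cold in NC567, 3 in Taiyan8, 2 for genotype at 0 h, 3 at 24 h and 1 for the ratio of folds. By sequence they were 2 and 1 for cold and 1 at 0 h, and in the exact sequences fixed in advance 0, 0 and 0, and 0 for the ratio. Both take in fewer families, but by sequence some reads outside the tobacco names are added. In NC567 at 0 h, 1 such sequence with the miR166 prefix had 32489 reads, against 24094 in the named miR166 family. With a minimum of 10 reads they were 5 for cold in Taiyan8 and 2 for the ratio, over miRNA reads 5 at 24 h, and without TMM and with 0 mismatches 2 and 2 for the ratio. Reversed single values were miR399 for cold in NC567 in mature matches (log2 fold -0.18) and the miR408 ratio in the shorter exact sequence fixed in advance (log2 0.36), against -1.81 in mature matches; the first follows from leaving out the precursor's other reads, and the cause of the second was not tested. Of the other fold values of named families, 106 stayed within their counting interval and 26 moved.

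Shares after cold minus 0 h, in percentage points for NC567 and Taiyan8, were 21 nt -0.992 and -3.46, 24 nt -0.255 and -0.0676, 31 to 34 nt 12 and 8.02, tRNA 12.5 and 8.45, rRNA -9.09 and -1.43, tobacco miRNA -1.04 and -4.35, snoRNA 0.0383 and -0.367. Over distinct sequences they were 21 nt 0.147 and -1.77, 24 nt 0.456 and -1.07, 31 to 34 nt 1.06 and 1.84, tRNA 1.86 and 3.22, rRNA -2.07 and 4.38, tobacco miRNA -0.269 and -1.38, snoRNA -0.0246 and -0.533. Among sequences read at least 2 times they were 21 nt -1.08 and -3.52, 24 nt -0.199 and -0.0251, 31 to 34 nt 12.3 and 8.38, tRNA 12.7 and 8.75, rRNA -9.29 and -1.83, tobacco miRNA -1.26 and -4.46, snoRNA 0.0564 and -0.365. Without rRNA, tRNA, snRNA and snoRNA, they were 21 nt 4.95 and 0.355, 24 nt 0.690 and 0.161, 31 to 34 nt 0.144 and 0.143. For reads of 18 to 30 nt they were 21 nt 3.27 and -2.49, 24 nt 0.492 and 0.475, tRNA 0.726 and 0.454, rRNA -5.31 and 4.74, tobacco miRNA 3.89 and -3.52, snoRNA 0.235 and -0.440. Where a denominator loses a class that moved, the other shares shift with it; beyond that the cause was not tested. The similarity of the cold responses kept its sign and a permutation p under 0.05, with r from 0.17 over 206 single sequences to 0.81. Depth limits families with few reads, such as miR397 (5 to 25 reads per library).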

Other observations

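The tests on the NC567 0 h library, on scaling of the 6 families, on the chamber and on reads of 15 to 18 nt, and the values at 35 to 50 nt, of mature and other reads and of sequences read in 1 genotype, were chosen after the results were seen. Mature reads of a family and its other precursor reads did not always move together. In NC567, mature miR399 reads went from 44 to 63 (log2 fold -0.28 with TMM) and its other reads from 30 to 299 (2.50), while in Taiyan8 the log2 folds were 1.49 and 1.55. For miR398, mature reads in Taiyan8 went from 485 to 962 (1.04) and its other reads from 119 to 44 (-1.37), against log2 folds of 1.45 and 1.22 in NC567. For miR169 the log2 folds of mature and other reads were -1.22 and -1.21 in NC567 and -1.47 and -1.23 in Taiyan8, and for miR482 they were 0.36 and -0.24, and 0.33 and -0.72.

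Some sequences were read in 1 genotype only. With at least 10 reads in both libraries of a genotype and 0 in both of the other, there were 32 for NC567 and 18 for Taiyan8, against 21 for cold only, 0 for 0 h only and 1 and 0 for the crossed pairs of libraries. Of all 771318 distinct sequences, 54678 were read in all 4 libraries and held 90.5% of the reads.

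In both genotypes miR398, miR399, miR408, miR169, miR477 and miR156, the called families with a shared log2 fold of at least 0.5 in size, a limit set after the folds were seen, had cold folds whose counting intervals exclude 1 in the same direction; with 0 mismatches only miR398 had a shared log2 fold of 0.35, and in mature matches only miR399 had 0.60, neither past the threshold (adjusted p = 0.27 and 0.62, 1.1e-09 to 0.27 and 1.1e-09 to 0.62 over 10 settings). The NC567 0 h library as the whole source is argued against, since the Taiyan8 pair shares no library with NC567. The 6 families farthest from 0 in the NC567 pair alone, which are the same 6, had a median Taiyan8 log2 fold of 1.09 in the NC567 direction. The highest of 10000 random lists of 6 other families was 0.32, but those lists hold none of the 6 and so set no chance level. The cut at 6 came from the shared test and the limit above, which used the Taiyan8 pair. The next family by NC567 fold, miR827 (-0.55), went the other way in Taiyan8 (0.27). Scaling moves all families alike. It is argued against by a gap of 1.11 log2 in Taiyan8 (0.84 from the interval bounds) between those of the 6 higher and those lower in NC567. For the other families 2 SD was 0.37, and the size of the gap has no test, since the cut at 6 used this pair too. Read length is argued against for direction only, by 6 of 6 keeping theirs with reads of 21 and 22 nt only. In NC567 at 0 h that filter kept 71 of 74 miR399 reads, which leaves little to change, and 286 of 1761 miR169 reads. Under it the shared test called 1 higher and 0 lower. A linear trend on GC content over 48 families was weak (r 0.13 in NC567 and 0.03 in Taiyan8). Taking it out moved the median absolute log2 fold of the 6 by only 0.0070 in NC567 and 0.0042 in Taiyan8. That median was then 1.39 and 1.09, against 0.45 and 0.37 for 2 SD of the others. The 6 were picked for large folds, so their lying above that limit cannot decide on GC content. The move into the chamber stays open with 0 libraries kept 24 h there without cold. A response to cold is thus a hypothesis that cannot be told apart from a response to the move. For miR479 and miR482 scaling stays open: 2 of 2 changed direction or lost their call under another scaling, but their Taiyan8 log2 folds of 0.18 and 0.31 are below the 0.39 by which leaving out TMM moved all families, so this decides nothing.

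Reads of 15 to 18 nt were fewer and tRNA reads of 31 to 34 nt more after cold. The short reads lay below a fold of 1 in 6 of 6 values over tobacco miRNA, tRNA and rRNA in the 2 genotypes, which is consistent with size selection or trimming that differed between the 0 h and 24 h libraries; a change in RNA breakdown was not tested. For the tRNA fragments the same explanation stays open: their log2 fold minus that of rRNA of the same length was 0.37 in NC567 and -0.12 in Taiyan8, while at 35 to 50 nt, where the log2 folds were 1.49 and 0.95 for tRNA and 1.36 and 0.91 for rRNA, both classes were higher, which goes with size selection. Nor is it settled whether a few sequences carried the change, since without the top 10 the log2 fold was 0.21 in Taiyan8 and 0.50 in NC567. Cold-induced tRNA cleavage remains an untested biological explanation.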
